A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

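RNA-seq and ribosome profiling libraries of budding yeast were analysed, 3 of each kind from untreated cultures and 3 of each kind from cultures that had earlier grown with 10 µM radicicol, an inhibitor of the chaperone Hsp90. By the protocol, 3 colonies were grown overnight, and the culture of each was divided between medium with and without the drug for another night. The labels do not say whether a replicate number marks the same colony in both treatments, so the models of RNA and of fragments left the number out. The cultures were then diluted to an OD600 of 0.001, grown for another 24 h and collected by filtration. RNA was poly(A)-selected and fragmented. Ribosome-protected fragments were made by RNase I digestion and purification of monosomes on a sucrose gradient. The density of the cultures at harvest was not given, and no spike-in was described, so every change below is relative to the other genes of the same library.

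The deposited values were raw counts of reads, 1 file per library. Per the file headers, the counts were made with featureCounts 1.6.2 on the forward strand and per exon feature, on an R64-1-1 annotation with a plasmid added. The settings left out reads that overlap more than 1 feature and reads that map to more than 1 place, so the counts of close paralogs and of genes that overlap on the same strand are uncertain. Per the submitters' processing notes, cutadapt 1.18, STAR 2.7.1a and SAMtools 1.9 were also used, with the genome build sacCer3. The authors also deposited a table of counts for the whole series, whose making is not stated in the file. Its totals came to between 98.3% and 99.1% of the totals of the per-library files, and it served as an alternative. No reads were processed here.

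Counts of the 7557 exon features were summed to 7130 gene identifiers, of which 396 had several features. Symbols were matched for 6048 identifiers from a table of RefSeq genes. The feature lengths were multiples of 3 for 96.4% of the identifiers, so counts in genes are mostly counts in coding sequence. Each library held between 737922 and 2481336 counts, and 3 counts in a library correspond to between 1.21 and 4.07 CPM. Such limits cover counting error only.

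Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and each comparison was tested with edgeR's robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. RNA and fragments were each compared between the treatments over 6 libraries. A change in translational efficiency, the ratio of fragments to RNA, was tested as the interaction of treatment and library type over all 12 libraries. Its model had no term for the culture, although RNA and fragment libraries of the same number and treatment were taken to share a culture. The levels of translational efficiency were log2 ratios of CPM with a pseudocount of 0.5 counts, formed within each treatment between the RNA and fragment libraries of the same number. For these ratios TMM scaling ran over all 12 libraries, while the CPM given for RNA and fragments were scaled within the 6 libraries of a type, so the ratios are not quotients of those CPM. Untreated levels and their list medians were then centred on the median gene of each culture. Means and standard deviations (SD) are over 3 libraries in normalised counts (CPM, counts scaled to a common library size), and SE is the standard error of a fitted log2 fold change. P-values of single genes measure the spread between the cultures of a treatment. Correlations between RNA and fragment changes are across genes, which are not independent replicates.

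27 gene lists with 852 matched members were tested with camera at a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the lists of a comparison. Camera at a preset correlation compares the genes of a list with the other genes, so its p-values do not measure the spread between cultures. Camera with a correlation estimated from the data and fry were run beside it. The lists covered chaperones, Hsp90 co-chaperones, general stress response, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, aminoacyl-tRNA synthetases, regulators of translation, amino acid biosynthesis, methionine and sulfur metabolism, glycolysis and fermentation, respiration, glucose-repressed genes, the proteasome, protein folding in the endoplasmic reticulum, pleiotropic drug resistance, cell wall integrity, phosphate starvation, the iron regulon, ergosterol synthesis, oxidative stress, mating, histones and S phase, mitotic genes, mitochondrially encoded genes and meiosis. 2 entries, ARG5,6 and an incomplete name, matched no gene. The list of mitochondrially encoded genes was not tested, since every feature of the mitochondrial chromosome had a count of 0 in every library.

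Genes were named by a rule. Among genes past the threshold with a mean of at least 10 CPM and no overlap between the values of the treatments, the rule took the 10 largest rises and the 10 largest falls of each comparison. With fewer than 5 calls in a comparison, it took the 5 smallest p-values. From each list it took up to 4 members with the largest change among those past the threshold, or the 2 most abundant where none passed. HSP82, HSC82, HSP104, SSA4, HSP26, PDR5 and GCN4 were always reported. Further list members that the text names were chosen after their values were seen. Groups, tests, lists, this rule and the alternatives were chosen before the data were examined, apart from the table of the whole series and a restriction to protein-coding genes, which were added afterwards.

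The alternatives were DESeq2 1.42.0 size factors and upper-quartile factors, the DESeq2 Wald test, limma-voom, no filter, a minimum mean count of 100, a test against a change of 1.2-fold, a threshold of 0.10, the replicate number as a block, and each replicate left out in turn. For translational efficiency, a term per culture and limma on the log2 ratios were also tried. The calls were tested on simulated data with 100 changed genes for each of 2 fold changes in each comparison. Simulated libraries were drawn independently, so the RNA and fragments of a culture shared no deviation. At 1.5-fold, 60% of the changed genes were recovered for RNA, 50% for fragments and 21% for translational efficiency. At 2-fold, the recovered shares were 93%, 85% and 58%. False calls made up 10% of the calls for RNA, 6.9% for fragments and 4.82% for translational efficiency.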

Results

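Gene expression and translation were measured in yeast cultures that had grown overnight with radicicol, an inhibitor of the chaperone Hsp90, and had then regrown for 24 h from a high dilution, beside cultures that never met the drug. The series title places the question in changes of translation that last after a passing loss of Hsp90 activity. The design text also mentions heat shock, but no sample was labelled as heat-shocked. Each of the 4 groups, untreated RNA, untreated ribosome-protected fragments, pre-treated RNA and pre-treated fragments, held 3 libraries. The untreated RNA libraries held 1961278, 2029914 and 737922 counts, and the pre-treated RNA libraries 2481336, 2203226 and 2067285. The fragment libraries held 1221485, 1476787 and 1155966 counts without the drug and 1500265, 1518514 and 1639436 after it. In untreated fragment libraries the small heat shock protein gene HSP26 took the largest share, between 3.03% and 3.32% of the counts, and in pre-treated fragment libraries the pyruvate decarboxylase gene PDC1 did, at 2.67% to 2.75%. Small nucleolar RNAs made up 0.59% of the counts in untreated RNA replicate 2 and between 1.06% and 1.30% in the other RNA libraries. In a principal component analysis of all 12 libraries, the first component, which parted RNA from fragments, held 83.0% of the variance, and the next, which parted untreated from pre-treated libraries, held 6.88%.

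The comparison of RNA asked which transcripts still differed after regrowth without the drug. The largest rise was that of PDC5 (YLR134W, chromosome XII, 410723 to 412414, R64-1-1), which encodes a minor isoform of pyruvate decarboxylase. It went from 138 ± 12.5 to 1217 ± 30.9 CPM (SD, n = 3), or 8.73-fold. SUL1 (YBR294W, chromosome II, 789235 to 791814), a high-affinity sulfate permease gene, rose 7.99-fold from 118 ± 8.36 to 940.3 ± 82.7 CPM. The sulfate activation gene MET3 rose 4.56-fold, and LEU1, a leucine synthesis gene, rose 4.01-fold. The largest fall was that of PHO84 (YML123C, chromosome XIII, 24037 to 25800), the high-affinity phosphate transporter gene, from 177 ± 12.7 to 36.5 ± 5.89 CPM, and SPS100, a spore wall gene, fell from 748 ± 46.1 to 198 ± 47.5 CPM.

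With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 738 of 5578 genes were called, 400 higher and 338 lower, and 64 of the higher and 15 of the lower differed by more than 2-fold. With upper-quartile factors the calls were 347 higher and 411 lower, so which direction held more genes depended on the scaling. The adjusted p was 4.43e-17 for PDC5, 1.73e-16 for SUL1, 1.00e-13 for MET3, 1.25e-13 for LEU1, 2.27e-12 for PHO84 and 4.35e-08 for SPS100. In each the 3 pre-treated libraries lay outside the range of the untreated ones, which the naming rule required of the largest changes. Other large rises were those of the permease gene SEO1 (log2 2.65, SE 0.20), CSS1 (2.35, SE 0.23), the serine deaminase gene CHA1 (2.28, SE 0.26), the S-methylmethionine permease gene MMP1 (2.03, SE 0.12) and the sulfatase gene BDS1 (1.87, SE 0.14). YOL163W also passed (2.11, SE 0.45, adjusted p = 0.0186), but not without any single untreated replicate (adjusted p = 0.0586, 0.0530 and 0.0647 without replicates 1, 2 and 3). Other large falls were those of FCY21 (-1.53, SE 0.25), the dihydroxyacetone kinase gene DAK2 (-1.39, SE 0.23), VHR2 (-1.20, SE 0.16), DPA10 (-1.14, SE 0.17), ECM13 (-1.05, SE 0.16), the cell wall protein gene SPI1 (-1.01, SE 0.11) and BCD1 (-0.97, SE 0.14). YMR175W-A fell as well (-1.16, SE 0.29, adjusted p = 0.0482), but its call ended without pre-treated replicate 1, 2 or 3 (adjusted p = 0.0703, 0.0876 and 0.126). The number of calls was 407 without pre-treated replicate 2, and 284 genes passed a test against a change of 1.2-fold.

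Of the 22 methionine and sulfur metabolism genes, 20 rose in RNA and 0 fell, with a median log2 change of 1.03. The same counts were found when adjusted over the list alone. The risers included the sulfite reductase genes MET5 and MET10, the sulfate reduction gene MET16, the S-adenosylmethionine synthetase genes SAM1 and SAM2 and the methionine permease gene MUP1. Camera gave an adjusted p = 3.68e-72, and an adjusted p = 0.0980 with an estimated correlation. Amino acid biosynthesis genes went both ways, with 17 of 50 higher and 4 lower (20 and 5 adjusted over the list alone) and a median of 0.15. LEU1, the glutamate synthase gene GLT1 (1.25, SE 0.11), and the serine synthesis genes SER1 (1.21, SE 0.10) and SER33 (1.05, SE 0.10) rose, while SER3, ILV5, ILV6 and LYS20 fell. SER3 overlaps the noncoding gene SRG1 on the same strand, so its count is uncertain. The list passed with camera (adjusted p = 1.65e-06; adjusted p = 0.465 with an estimated correlation). Of the 22 aminoacyl-tRNA synthetase genes, 6 rose, among them THS1 (0.57, SE 0.11) and CDC60 (0.54, SE 0.11), and 0 fell (10 and 1 adjusted over the list alone), with a camera adjusted p = 0.0158, or adjusted p = 0.502 with an estimated correlation. This call ended without untreated replicate 1 (adjusted p = 0.0770).

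Among histone and S phase genes, 9 of 15 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.40, and the largest changes were those of the histone genes HTB2 (0.97, SE 0.14) and HTA2 (0.88, SE 0.12). Among mitotic genes, 8 of 16 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.47; these included the bud neck gene BUD4 (0.96, SE 0.16), the cyclin gene CLB1 (0.83, SE 0.14) and the transcription factor gene SWI5 (0.69, SE 0.15). Both lists had a camera adjusted p = 4.79e-05, and neither passed with an estimated correlation (adjusted p = 0.215). Of 35 proteasome genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.00142; adjusted p = 0.484 with an estimated correlation). In the list of protein folding in the endoplasmic reticulum, 6 of 21 genes rose and 0 fell, also when adjusted over the list alone. They included the oxidase gene ERO1 (0.97, SE 0.11), the nucleotide exchange factor gene SIL1 (0.93, SE 0.17) and KAR2, the Hsp70 of this compartment (0.65, SE 0.10). The median of that list was 0.08 (camera adjusted p = 0.0222; adjusted p = 0.215 with an estimated correlation), and its call ended without untreated replicate 2 (adjusted p = 0.0529). Of 20 mating genes, 5 rose and 1 fell (the same adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0300; adjusted p = 0.331 with an estimated correlation). The risers were the pheromone genes MF(ALPHA)1 and MFA1, the pheromone receptor gene STE2, the transporter gene STE6 and the pheromone protease gene BAR1, and PRM4 fell. The mating call ended without untreated replicate 2 (adjusted p = 0.0529), untreated replicate 3 (0.0696) or pre-treated replicate 1 (0.0656).

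Glucose-repressed genes, which yeast uses on carbon sources other than glucose, were lower. Of 28 measured members, 14 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 1.93e-08; adjusted p = 0.111 with an estimated correlation). The lactate transporter gene JEN1 fell by 0.95 on the log2 scale (SE 0.13), the peroxisomal oxidase gene POX1 by 0.95 (SE 0.20) and the malate synthase gene MLS1 by 0.92 (SE 0.16). Glycolysis and fermentation genes went both ways, and the list's median of -0.11 had the opposite sign to its mean of 0.10 and to the Up direction of the test, which did not pass (adjusted p = 0.393). PDC5, the glucose transporter gene HXT1 (1.63, SE 0.12) and the enolase gene ENO2 rose, while the alcohol dehydrogenase gene ADH1 (-0.86, SE 0.10), the glyceraldehyde phosphate dehydrogenase gene TDH1 (-0.70, SE 0.13), ENO1 and HXT3 fell.

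Chaperone genes fell more often than they rose. Of 28, 6 fell and 1 rose, also when adjusted over the list alone, and the list did not pass (median -0.09, adjusted p = 0.0571). HSP26 fell from 18080.1 ± 2671 to 11055 ± 1042 CPM (log2 -0.71, SE 0.12), SSA3 by 0.74 (SE 0.09) and SSA4 by 0.58 (SE 0.09). HSP82 (YPL240C), the stress-inducible Hsp90 gene, fell from 2625 ± 244 to 2088 ± 105 CPM (log2 -0.33, SE 0.10, adjusted p = 0.0309), but this call ended without untreated replicate 1 or 2 (adjusted p = 0.103 and 0.0702) and without pre-treated replicate 1, 2 or 3 (0.138, 0.195 and 0.0622). HSC82 (YMR186W), the constitutive Hsp90 gene, had a log2 change of -0.19 (SE 0.11, adjusted p = 0.266) and passed without untreated replicate 3 (adjusted p = 0.0358), and the disaggregase gene HSP104 had one of -0.25 (SE 0.11, adjusted p = 0.151). GCN4, which encodes the transcription activator of amino acid synthesis genes, fell by 0.46 (SE 0.10, adjusted p = 0.00134), and the drug efflux pump gene PDR5 rose by 0.61 (SE 0.10, adjusted p = 7.25e-05).

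The other lists did not pass in RNA. Of 137 cytosolic ribosomal protein genes, 2 rose and 10 fell, with a median of -0.08 (adjusted p = 0.0571), and the genes that fell most were RPL22B (-0.88, SE 0.15) and RPS14B (-0.59, SE 0.10). Counts of 0 higher and 2 lower were found among 72 mitochondrial ribosomal protein genes (adjusted p = 0.0854), 4 and 3 among 57 ribosome biogenesis genes (0.341), 1 and 2 among 40 translation factor genes (0.580) and 0 and 4 among 24 regulators of translation (0.0917). The counts were 0 higher and 1 lower of 12 Hsp90 co-chaperone genes (adjusted p = 0.937), where the median of 0.01 turned to -0.03 with upper-quartile factors. In general stress response 2 of 30 were higher and 6 lower (0.0822), with the stress genes DDR2 and YGP1 among the lower, and in respiration 6 of 46 and 5 (0.862). In pleiotropic drug resistance 3 of 20 were higher and 2 lower (0.0822), with the efflux pump genes ATR1 (0.99, SE 0.15) and PDR12 (0.92, SE 0.10) higher. In cell wall integrity 5 of 24 rose and 5 fell (0.804), the mannoprotein gene CWP1 rising by 1.82 (SE 0.20) and the structural protein gene SED1 falling. Among phosphate genes 2 of 15 rose and 2 fell (0.534), and the largest rise there was that of PHO3 (1.71, SE 0.13), whose acid phosphatase is known to respond to thiamine, not phosphate. The iron regulon had 4 of 18 higher and 5 lower (0.534), ergosterol synthesis 2 of 24 and 5 (0.105), oxidative stress 3 of 20 and 5 (0.883), and meiosis genes 1 of 11 and 1 (0.0822). Median and mean differed in sign for respiration (-0.04 and 0.02), the iron regulon (0.07 and -0.01) and oxidative stress (-0.09 and 0.04), and the test direction was Down for these and for the co-chaperones. With 1 library left out, some of these lists passed: chaperones without untreated replicate 1 (adjusted p = 0.0419), untreated replicate 3 (0.0220) or pre-treated replicate 2 (0.0378), ribosomal proteins without untreated replicate 1 (0.0225), untreated replicate 2 (0.0296) or pre-treated replicate 1 (0.00262), and ribosome biogenesis without untreated replicate 1 (0.00648). The same held for general stress response without untreated replicate 3 (0.00345) or pre-treated replicate 2 (0.0383), drug resistance without pre-treated replicate 1 (0.0460) or 2 (0.0431), and meiosis without pre-treated replicate 1 (0.0178) or 2 (0.0378).

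**Figure D1:**
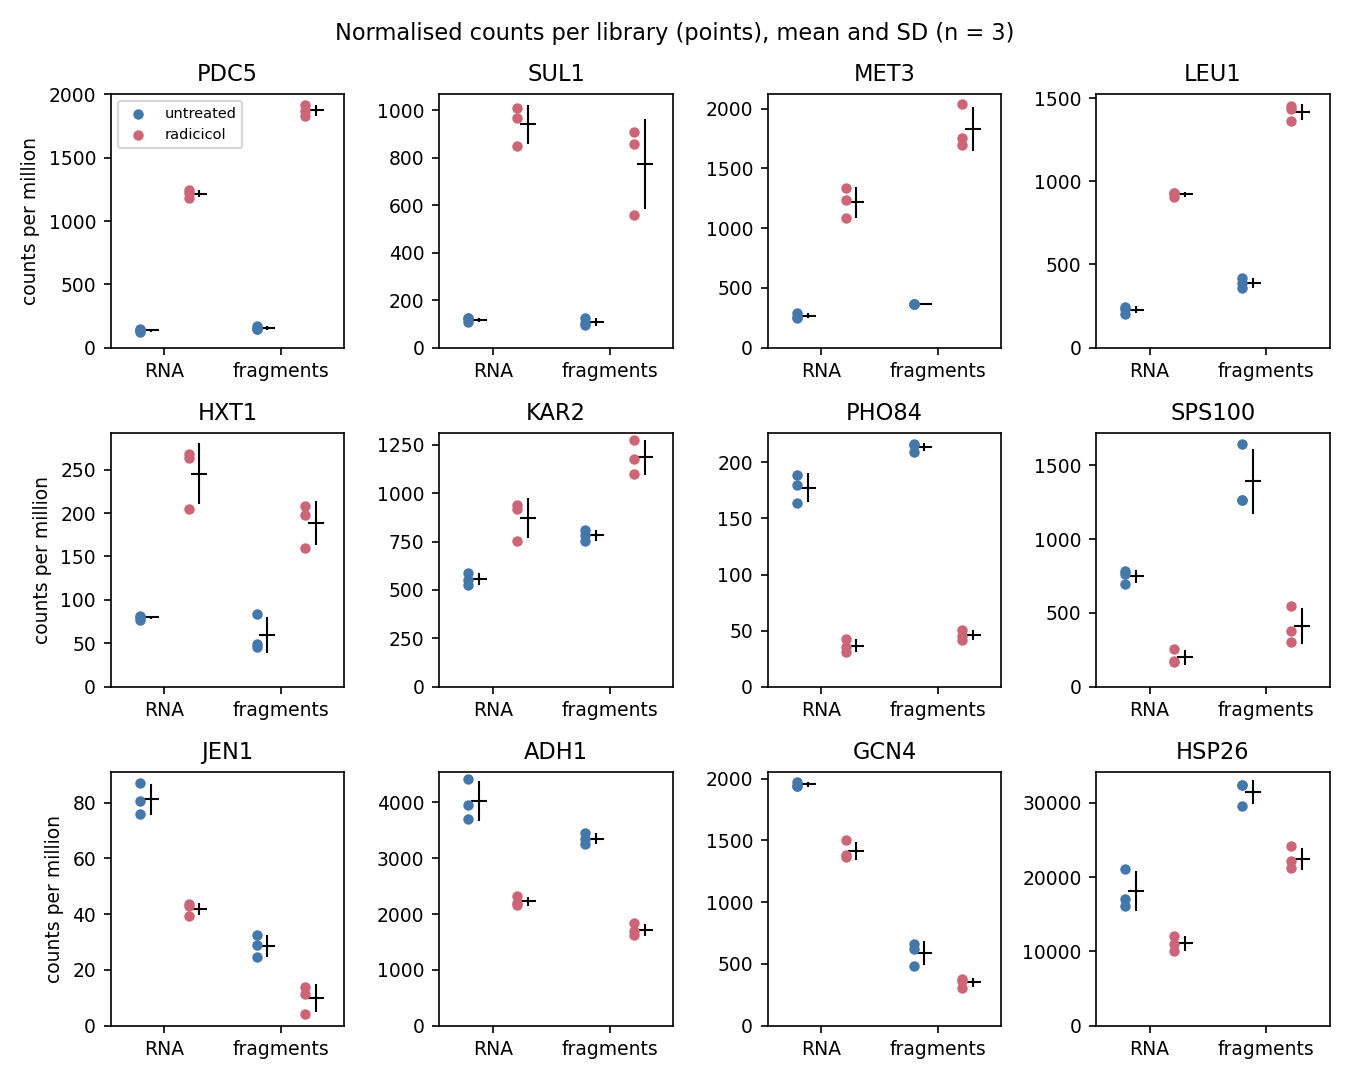
Normalised counts (CPM) of 12 genes in each of the 12 libraries (points, blue untreated and red pre-treated with radicicol) for RNA and ribosome-protected fragments, with the mean and SD of 3 libraries beside them and each axis starting at 0. PDC5 RNA went from 138 to 1217 CPM on average, and PHO84 RNA from 177 to 36.5 CPM.

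The comparison of ribosome-protected fragments asked which genes had more or fewer translating ribosomes relative to the rest after regrowth. PDC5 rose from 157 ± 13.7 to 1873 ± 43.4 CPM (SD, n = 3), or 12-fold, followed by SEO1 (10.8-fold), CWP1 (10.4-fold), CHA1 (9.59-fold) and BDS1 (9.24-fold). Untreated fragments on CWP1 were few and spread widely, at 6.72 ± 4.29 CPM. In untreated replicate 1 they stood at 2.40 CPM, where 3 counts correspond to 2.46 CPM. Those on CHA1 were also few, at 3.32 ± 0.106 CPM. The size of these 2 rises, and so their rank, is therefore uncertain. For CWP1 the log2 change ranged from 3.01 to 3.86 over the alternatives. MET3 rose 5.03-fold, from 364 ± 1.57 to 1828 ± 184 CPM, and LEU1 3.64-fold, from 388 ± 28 to 1415 ± 48.9 CPM. PHO84 fell from 214 ± 3.70 to 45.7 ± 4.41 CPM and JEN1 from 28.6 ± 4.02 to 9.87 ± 5.13 CPM.

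In the quasi-likelihood test with Benjamini-Hochberg adjustment, 681 of 5090 genes were called, 434 higher and 247 lower, and 95 of the higher and 22 of the lower differed by more than 2-fold. With upper-quartile factors the calls were 364 higher and 330 lower, so the size of the excess of higher genes depended on the scaling. The adjusted p was 4.67e-20 for PDC5, 1.25e-06 for SEO1, 6.42e-06 for CWP1, 2.84e-16 for MET3, 1.27e-14 for LEU1 and 1.72e-13 for PHO84. Other large rises were those of CSS1 (log2 3.09, SE 0.20), SUL1 (2.85, SE 0.21), the homocysteine methyltransferase gene MHT1 (2.64, SE 0.21), the amino acid permease gene AGP3 (2.40, SE 0.19) and ZPS1 (2.33, SE 0.12). Other large falls were those of DAK2 (-1.79, SE 0.22), the acetyl-CoA synthetase gene ACS1 (-1.71, SE 0.28), SER3 (-1.41, SE 0.11), the isocitrate lyase gene ICL1 (-1.35, SE 0.17), YPR145C-A (-1.28, SE 0.26), CIT3 (-1.21, SE 0.27) and PEX18 (-1.20, SE 0.21). SPS100 fell by 1.77 (SE 0.24, adjusted p = 0.00700), and that call ended without untreated replicate 1 (adjusted p = 0.0521). The number of calls was 442 without pre-treated replicate 2, and 312 genes passed a test against 1.2-fold.

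Sulfur genes led the lists again. Of 22 methionine and sulfur metabolism genes, 21 rose and 0 fell, also when adjusted over the list alone, with a median of 1.21 (camera adjusted p = 6.81e-75; adjusted p = 0.0708 with an estimated correlation). Of 50 amino acid biosynthesis genes, 21 rose and only SER3 fell (24 and 2 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 1.5e-09; adjusted p = 0.394 with an estimated correlation), and GLT1 rose by 2.09 (SE 0.13) and SER33 by 1.23 (SE 0.09). Of 22 aminoacyl-tRNA synthetase genes, 11 rose and 0 fell (14 and 0 adjusted over the list alone), with THS1 at 0.56 (SE 0.09) and a median of 0.28 (camera adjusted p = 0.000338; adjusted p = 0.394 with an estimated correlation). Of 21 genes of protein folding in the endoplasmic reticulum, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 9.81e-05; adjusted p = 0.312 with an estimated correlation). The largest rise there was that of HAC1 (1.93, SE 0.14), the transcription factor gene of the unfolded protein response, followed by ERO1 (1.06, SE 0.11) and SIL1 (0.91, SE 0.20).

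Fragments on mitotic genes rose for 10 of 16 and fell for 0 (12 and 0 adjusted over the list alone), with DSE2 at 0.92 (SE 0.10) and CLB2 at 0.79 (SE 0.19), a median of 0.52 and a camera adjusted p = 5.61e-07 (adjusted p = 0.284 with an estimated correlation). Histone and S phase genes rose for 6 of 15 and fell for 0 (8 and 0 adjusted over the list alone), with HTB2 at 1.28 (SE 0.13) and RNR1 at 0.67 (SE 0.10), a median of 0.34 and a camera adjusted p = 4.78e-06 (adjusted p = 0.284 with an estimated correlation). Cell wall genes rose for 10 of 23 and fell for 3 (12 and 5 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.000238; adjusted p = 0.394 with an estimated correlation). CWP1, CIS3 (1.00, SE 0.10), the glucanase gene SCW4 (0.74, SE 0.08) and PIR1 (0.67, SE 0.09) rose, and PST1, YPS1, which encodes a protease, and PIR3 fell. Glycolysis and fermentation genes rose for 6 of 19 and fell for 3 (6 and 4 adjusted over the list alone, 4 and 4 with upper-quartile factors), with a median of 0.09, a mean of 0.31 and a camera adjusted p = 0.000238 (adjusted p = 0.394 with an estimated correlation). The risers were PDC5, the transporter gene HXT1 (1.68, SE 0.18), ENO2 (0.80, SE 0.07), PDC1, TDH2 and GPM1, and ADH1 (-0.96, SE 0.08), TDH1 and HXT3 fell. Of 17 mating genes, 6 rose, among them the agglutinin gene AGA1 (1.07, SE 0.26) and BAR1 (1.06, SE 0.11), and 1 fell (7 and 1 adjusted over the list alone), with a camera adjusted p = 0.00288 (adjusted p = 0.329 with an estimated correlation). The proteasome list, with 5 of 35 higher and 0 lower (the same adjusted over the list alone, 2 and 0 with upper-quartile factors), passed narrowly with a median of 0.15 (camera adjusted p = 0.0483, or 0.394 with an estimated correlation). Its call ended without untreated replicate 3 (adjusted p = 0.0656) or pre-treated replicate 1 (0.0799) or 2 (0.105), with the replicate number as a block (0.0682) and with the table of the whole series (0.0507).

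Glucose-repressed genes fell for 13 of 23 and rose for 0 (16 and 0 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 1.5e-09; adjusted p = 0.115 with an estimated correlation). ACS1, JEN1 and ICL1 led them, and the gluconeogenesis gene PCK1 fell by 1.77 (SE 0.45), a call that ended without pre-treated replicate 2 (adjusted p = 0.0717). Mitochondrial ribosomal protein genes passed in the Down direction with a median of -0.21 although only 2 of 72 were called, MRPL15 and RSM22, both lower, and 0 when adjusted over the list alone (camera adjusted p = 0.00375, or 0.284 with an estimated correlation). The call was lost in 6 of 16 alternatives for MRPL15 and in 10 of 16 for RSM22. The 137 cytosolic ribosomal protein genes did not pass, with 7 higher, 1 lower and a median of 0.03 (camera adjusted p = 0.804). With upper-quartile factors 6 were higher and 5 lower, and the median turned to -0.01. Without untreated replicate 1 they passed in the Down direction (median -0.06, adjusted p = 0.0208), and without untreated replicate 2 in the Up direction (median 0.11, adjusted p = 0.0279). Ribosome biogenesis genes (3 of 57 higher, 3 lower, adjusted p = 0.316) passed in the Down direction without untreated replicate 1 (adjusted p = 0.0227) or pre-treated replicate 1 (0.0360).

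Fragments on HSP82 had a log2 change of -0.04 (SE 0.09, adjusted p = 0.860) and those on HSC82 of 0.21 (SE 0.08, adjusted p = 0.0745). HSP104 fell by 0.34 (SE 0.07, adjusted p = 0.000961), HSP26 by 0.48 (SE 0.07) and SSA4 by 0.62 (SE 0.08), while PDR5 rose by 0.68 (SE 0.08). GCN4 fell from 588 ± 94.0 to 349.7 ± 38.5 CPM (log2 -0.75, SE 0.11, adjusted p = 2.80e-05). Of the 28 chaperone genes, 3 rose and 6 fell, and the list did not pass (median 0.05, mean -0.02, test direction Down, adjusted p = 0.328). The co-chaperone genes did not pass either (median -0.03, adjusted p = 0.804), with a change of -0.07 (SE 0.07) for STI1.

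**Figure D2:**
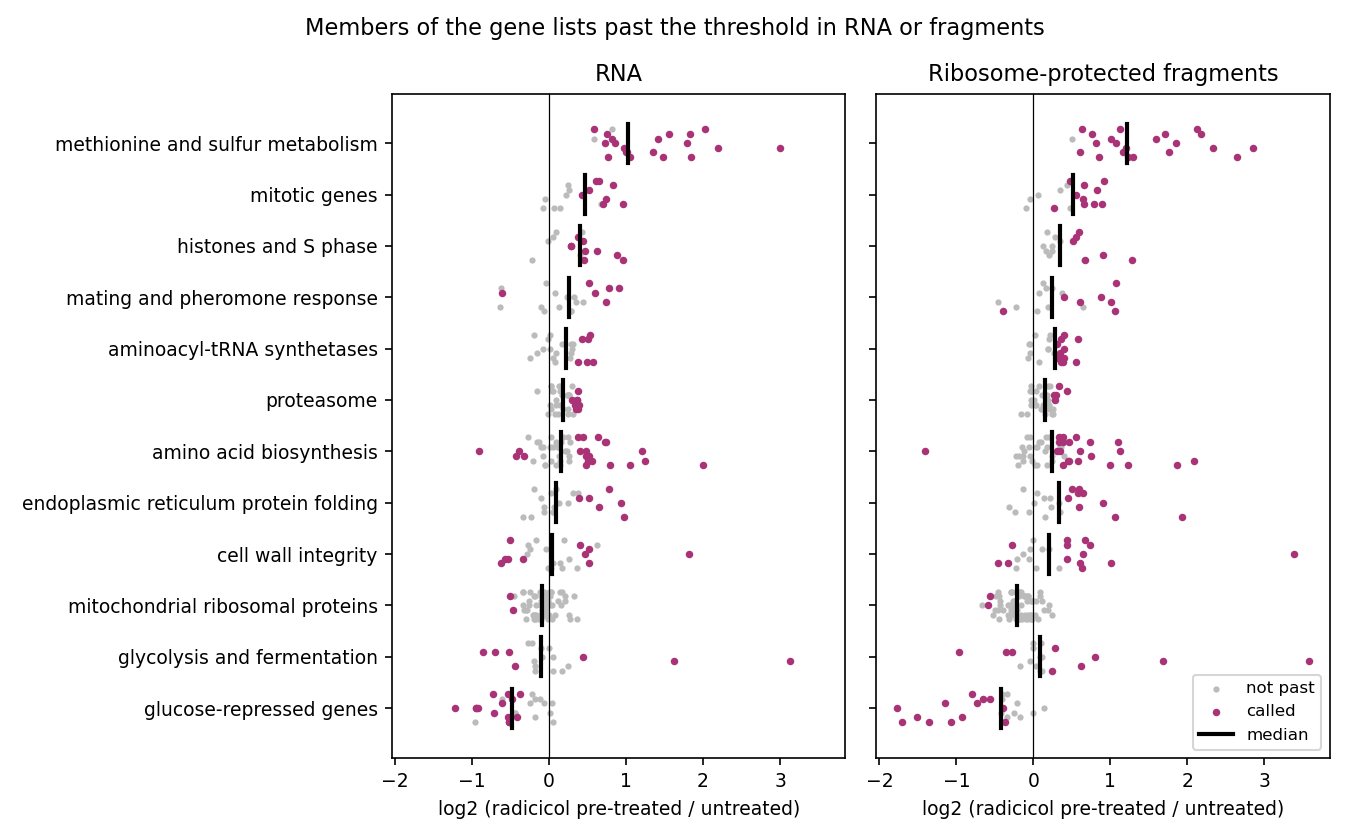
Log2 fold changes of the members of the 12 gene lists that passed in RNA or in fragments (points, purple where the gene was called at an adjusted p under 0.05), with the median of each list as a bar. Medians of methionine and sulfur metabolism were 1.03 in RNA and 1.21 in fragments, and those of glucose-repressed genes -0.49 and -0.42.

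Fragments followed RNA for most of the genes called. Among 5070 genes tested in both, 256 were higher in both and 131 lower in both, where independent calls would give 33.2 and 15.2, and 0 were called in opposite directions. An RNA and a fragment library share a culture, so the calls are not independent and these figures are no test. PDC5, SUL1, MET3 and LEU1 were higher in both, and PHO84, SPS100 and DAK2 lower in both. The fold changes correlated across genes with Pearson's r of 0.70 and Spearman's rho of 0.553, and with an r of 0.860 among the 2026 genes with a mean count of at least 100 in both. Of 316 genes called in RNA alone, 277 had the same sign in fragments, and of 292 called in fragments alone, 260 had the same sign in RNA. Of the 995 genes called in either, 1 also passed the test of translational efficiency in the model with no culture term, so the other calls in RNA or fragments alone were not shown by it to differ between the library types. With a term per culture, 29 genes passed that test in place of 1.

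**Figure D3:**
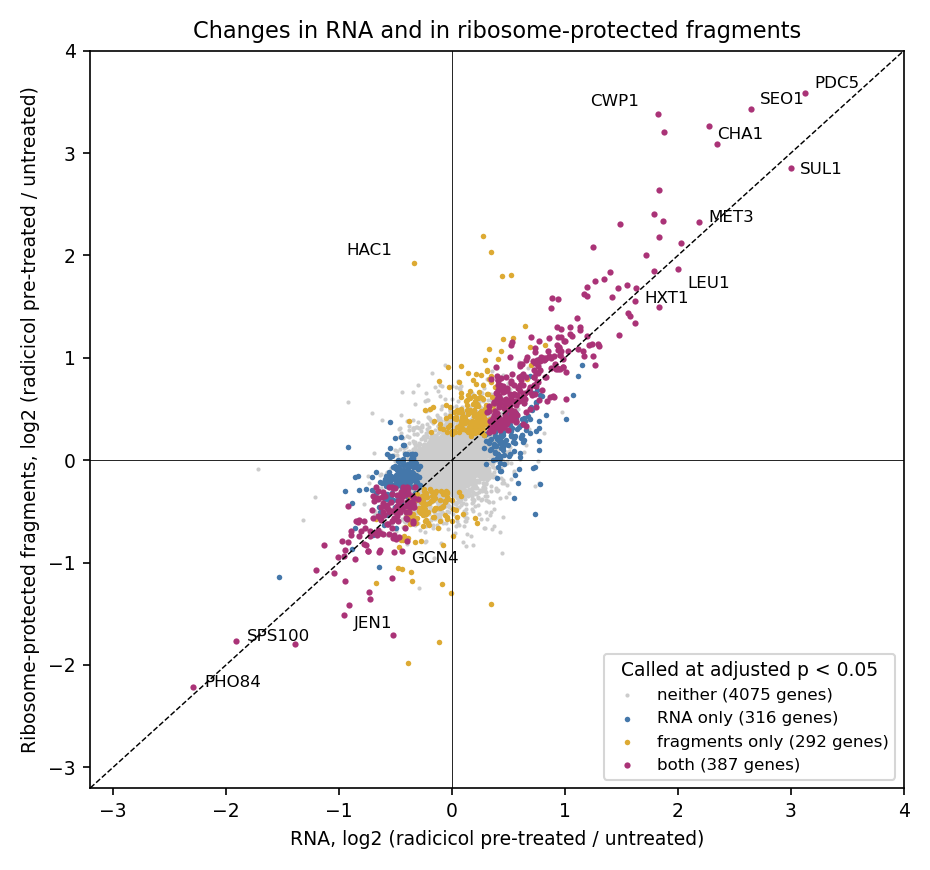
Log2 fold change of ribosome-protected fragments (vertical) against that of RNA (horizontal) for 5070 genes, each point a gene, coloured by where it was called, with the dashed line marking equal change. The 387 genes called in both changed in the same direction in both, and HAC1 was at -0.34 in RNA and 1.93 in fragments.

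Translational efficiency in untreated cells gave the level from which changes were measured. Levels are relative to the median gene of each culture, and they spanned 14.6-fold between the 5th and 95th percentiles of 5552 features. Of these, 5362 were protein-coding. The span was not computed without the others, so RNAs that are not translated can widen it at the low end. Cell wall genes had the highest list median, 0.89 ± 0.17 on the log2 scale (SD, n = 3), followed by mitotic genes (0.84 ± 0.14), respiration (0.80 ± 0.05), general stress response (0.72 ± 0.03) and chaperones (0.68 ± 0.03). Meiosis genes had the lowest (-0.88 ± 0.46), and ribosomal protein genes had -0.32 ± 0.20. Of the meiosis list, 10 genes were measured for this ratio but 3 passed the filter for fragments alone, so low fragment counts can set its level. GCN4, whose translation is held back by upstream open reading frames, stood at -1.31 ± 0.25, HSP104 at 1.56 ± 0.20 and HSP26 at 1.24 ± 0.16. HAC1, whose RNA is known to be kept from translation by its intron until the kinase Ire1 starts its splicing, stood at -5.03 ± 0.37. This was near the 2.5th percentile of all the features, including those that were not protein-coding.

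The comparison of translational efficiency asked which genes gained or lost ribosomes beyond the change in their RNA, and HAC1 was the gene that passed in the interaction model. HAC1 (YFL031W, chromosome VI, exons 75179 to 75839 and 76092 to 76147) rose by 2.27 on the log2 scale (SE 0.26, adjusted p = 0.00143 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its fragments rose from 32.0 ± 0.821 to 122 ± 13.7 CPM, while its RNA went from 1461 ± 393 to 1157 ± 17.4 CPM and was not called (log2 -0.34, SE 0.17, adjusted p = 0.237). The log2 ratio, scaled over all 12 libraries and so not the quotient of these CPM, went from -5.07 ± 0.36 to -2.84 ± 0.18, and each pre-treated culture lay above each untreated one. HAC1 overlaps YFL032W on the same strand, so reads over both were not counted. The call ended without untreated replicate 3 (2.29, adjusted p = 0.0915) and with limma on the log2 ratios (2.22, adjusted p = 0.447), and the adjusted p ranged from 8.57e-17 to 0.447 over 19 alternatives.

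**Figure D4:**
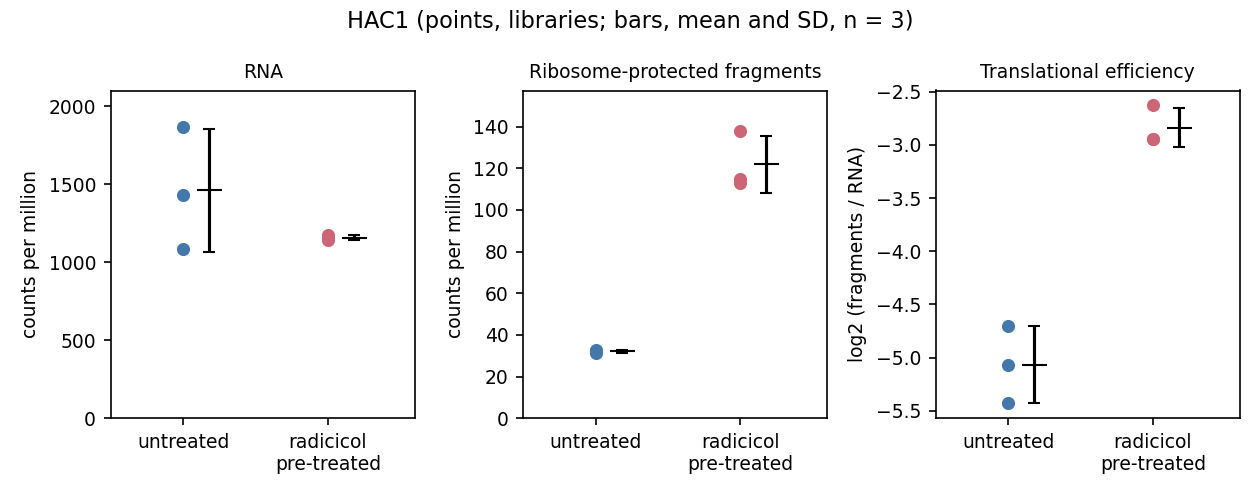
HAC1 in each library (points, blue untreated and red pre-treated with radicicol) as RNA and ribosome-protected fragments in CPM, and as the log2 ratio of fragments to RNA after scaling over all 12 libraries, with mean and SD of 3. RNA averaged 1461 and 1157 CPM, fragments 32.0 and 122 CPM, and the log2 ratio -5.07 and -2.84.

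The next smallest p-values belonged to genes that did not pass in this model, which had no term for the culture that an RNA and a fragment library share. These were GLT1 (0.85, SE 0.18, adjusted p = 0.0640), BDS1 (1.35, SE 0.28, adjusted p = 0.0640), JIP5 (-1.74, SE 0.38, adjusted p = 0.0778) and the translocon gene SEC61 (0.71, SE 0.16, adjusted p = 0.106). With a term per culture 29 genes passed, 26 higher and 3 lower, among them GLT1 (adjusted p = 0.0193), BDS1 (0.00343), JIP5 (0.0193), SEC61 (0.0193) and HAC1. With no filter 6 passed, including GLT1 (adjusted p = 0.0265), BDS1 (0.0149), JIP5 (0.0265) and SEC61 (0.0472), while limma on the log2 ratios called 0. BDS1 also passed with the replicate number as a block (adjusted p = 0.0147) and without pre-treated replicate 1 (1.39, adjusted p = 0.0166). The Hsp90 genes had changes of 0.31 (HSP82, SE 0.14, adjusted p = 0.568) and 0.41 (HSC82, SE 0.13, adjusted p = 0.345), and GCN4 of -0.28 (SE 0.14, adjusted p = 0.625). HSP104 (-0.08), SSA4 (-0.03), HSP26 (0.24) and PDR5 (0.09) did not pass either. At an unadjusted p under 0.05 the count was 439 of 5552 genes, and after adjustment the DESeq2 Wald test and limma-voom each called 1 and the threshold of 0.10 gave 4. The test recovered 58% of simulated 2-fold changes and 21% of 1.5-fold changes. That simulation gave 83 calls, where the data gave 1. Adjustment is stricter when fewer genes pass, so these shares may be too high for the data.

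As groups, cell wall genes (median 0.25, camera adjusted p = 5.63e-09), glycolysis and fermentation genes (0.23, adjusted p = 1.61e-06) and cytosolic ribosomal protein genes (0.09, adjusted p = 0.000369) shifted up in translational efficiency relative to other genes, each with an adjusted p = 0.686 with an estimated correlation. Their adjusted p with fry was 0.379, 0.408 and 0.559. No member of these lists was called by edgeR over all genes, and 4, 1 and 0 were higher when adjusted over the list alone. HSP150 (0.29, SE 0.14) and SED1 (0.37, SE 0.15) were the most abundant cell wall genes, and PDC1 had 0.38 (SE 0.14). The shift of the ribosomal protein genes ended without untreated replicate 1 (median -0.000214, adjusted p = 0.944), and the untreated level of this list differed between the cultures, at -0.53, -0.12 and -0.32. Lists below the threshold included chaperones (0.07, adjusted p = 0.0726), amino acid biosynthesis (0.06, adjusted p = 0.0726), methionine and sulfur metabolism (0.16, adjusted p = 0.0655), protein folding in the endoplasmic reticulum (0.04, adjusted p = 0.0655) and mitochondrial ribosomal proteins (-0.06, adjusted p = 0.0726). Methionine and sulfur metabolism passed without untreated replicate 3 (adjusted p = 0.0223), pre-treated replicate 1 (0.0121) or pre-treated replicate 3 (0.0438) and with the replicate number as a block (0.0406), and amino acid biosynthesis without untreated replicate 3 (0.0223) or pre-treated replicate 3 (0.0438). Mitochondrial ribosomal proteins passed in the Down direction without untreated replicate 1 (0.0287) or 3 (0.0464), aminoacyl-tRNA synthetases and endoplasmic reticulum folding in the Up direction without untreated replicate 1 (0.0209 and 0.0273), the iron regulon without untreated replicate 3 (0.0223), and glucose-repressed genes in the Down direction without pre-treated replicate 3 (0.0438).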

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

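The tests on HAC1 in this part were chosen only after the result was seen. HAC1 stood out because the pre-treatment's effect on its fragments differed from the effect on its RNA by 2.27 on the log2 scale in the interaction test (SE 0.26, adjusted p = 0.00143), higher in 3 of 3 pre-treated cultures. Between the exons, counting per exon feature leaves out only reads that overlap both. Exon 1 alone held 122 of the 125 untreated fragments and 541 of the 557 pre-treated ones and gave a change of 2.19 (SE 0.22). Exon 1 held nearly all fragments in both treatments, so its change restates that of the whole gene. That change cannot show whether such counting had a part, and reads at the exon boundary could not be told apart from the rest. Low counts in untreated libraries are argued against, because the ratio of 3.82 between the library-scaled sums had an exact Poisson 95% interval of 3.14 to 4.67, which covers counting error only. A candidate explanation is that more spliced HAC1 RNA was translated, but exon 2 held too few fragments, 3 of the untreated and 16 of the pre-treated ones, to decide it (Fisher's exact test of exon 2 against exon 1, two-sided p = 1, odds ratio 1.2, 95% interval 0.337 to 6.54). In RNA, exon 2 held 522, 336 and 171 untreated counts beside 3040, 1781 and 913 on exon 1. The pre-treated counts were 394, 344 and 351 beside 2466, 2190 and 2152. These RNA counts were not tested for a change in splicing. Reads across the splice junction were not in the deposited counts, so more spliced RNA and more initiation on the same RNA cannot be told apart, and a lasting effect of the radicicol treatment itself stays open as an untested explanation.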

How the results depend on the processing

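The table of the whole series and the restriction to protein-coding genes were chosen only after the data were seen, and each kept all 3 gene counts within 1.5 times the reported ones. The count of genes was 738 for RNA and ranged from 407 (without pre-treated replicate 2) to 743 with 1 replicate left out; it was 284 when tested against 1.2-fold. For fragments, 681 became 442 (without pre-treated replicate 2) to 667, and 312 against 1.2-fold. The 1.2-fold test asks for larger changes, which shows why fewer passed; for the left-out replicate, the cause was not tested. The other settings gave from 492 to 1039 genes for RNA and from 454 to 889 for fragments, the lowest with the DESeq2 Wald test and the highest at a threshold of 0.10. Translational efficiency had 1 call with edgeR, 6 with no filter, 4 at a threshold of 0.10, 29 with a term per culture (the culture replicate block; 26 higher and 3 lower, HAC1 among them) and 0 with limma on the log2 ratios (465 at an unadjusted p under 0.05). It had 0 (without untreated replicate 3) to 3 (without pre-treated replicate 1) with 1 culture left out. The looser threshold shows its own cause; for the others, the cause was not tested. The number of lists past the threshold was 9, 12 and 3 for RNA, fragments and translational efficiency. It was 0, 0 and 0 with an estimated correlation (which was above 0.01 for most of these lists), 11, 13 and 0 with fry, and 8 to 13, 11 to 14 and 3 to 7 with 1 replicate left out. Endoplasmic reticulum folding in RNA lost its call although its estimated correlation was -0.0095, and the cause of these losses was not tested. Ribosomal protein genes changed sign without untreated replicate 1, with medians of -0.0638 in fragments (adjusted p = 0.0208; highest 0.109, without untreated replicate 2) and -0.000214 in translational efficiency (adjusted p = 0.944; highest 0.205, without untreated replicate 2); the cause was not tested. The correlation of RNA and fragment changes across genes was 0.860 for genes with a mean count of at least 100, where sampling noise is smaller. The fold between the 5th and 95th percentiles of untreated translational efficiency, over all features tested, was 14.5 to 15.9 with 1 replicate left out. With the replicate number as a block (replicate block), 673, 628 and 2 genes and 9, 11 and 4 lists were called. The block ended the calls of RRP9, NGR1 and TPO1 in RNA and of RSM22, RPN12 and PUP2 in fragments. By the protocol each colony was divided between the treatments, but the labels do not tie the numbers to colonies. Across treatments same-numbered deviations correlated at 0.01 to 0.08 for RNA and -0.12 to 0.02 for fragments. Within a treatment, 6 of 6 RNA libraries correlated best with the fragment library of their own number. Those correlations were 0.05 to 0.08 for untreated and 0.11 to 0.18 for pre-treated cultures. No such ranking was made across treatments, so a colony shared by a number there is neither shown nor excluded. Of the settings run for the named genes, the call was lost in 132 of 1868 cases for RNA and 96 of 1757 for fragments, with 0 changes of direction among called genes. The cases include the looser threshold and named genes that were not called, where no call could be lost. Most named genes were also chosen for large changes, so these counts do not describe all calls.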

Other observations

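The gene groups of the next paragraphs and the tests of both patterns below were chosen only after their values were seen. Of 11 ADE genes of purine synthesis, 10 were called higher in RNA and in fragments by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The ADE genes were not tested as a group. ADE57 rose 2.23-fold in RNA and 2.09-fold in fragments, ADE12 2.19-fold and 2.41-fold, and ADE1 2.08-fold and 2.32-fold, while ADE16 had log2 changes of -0.01 (SE 0.10) and -0.13 (SE 0.08). The glycine cleavage and one-carbon genes GCV1, GCV2, GCV3, SHM2 and MTD1 were named because they were higher, by 1.86-fold to 2.25-fold in RNA. Sulfur-related genes outside the fixed list, SEO1, BDS1, JLP1, OPT1, YCT1, DUG3 and GRX8, were named for the same reason, with rises of 2.25-fold to 6.26-fold in RNA, and so were MET32, a transcription factor gene of the sulfur pathway (2.40-fold and 3.37-fold), and MET30, whose ubiquitin ligase restrains it (1.77-fold and 1.98-fold).

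Hexose transporter genes went both ways. HXT1 rose 3.09-fold in RNA and 3.21-fold in fragments and HXT2 1.84-fold and 3.00-fold, while HXT3, HXT4 and HXT5 fell, by 0.52, 0.78 and 0.48 on the log2 scale in RNA. The fatty acid desaturase gene OLE1 fell by 0.95 in RNA and 0.87 in fragments. The mating-type endonuclease gene HO rose 2.81-fold and 4.95-fold, the IMP dehydrogenase gene IMD2 2.99-fold and 2.66-fold, and the amino acid permease gene DIP5 2.28-fold and 3.23-fold. Of 13 thiamine pathway genes measured in RNA, THI6 rose and THI2 fell, and in fragments THI6 and THI21 rose of 9 measured, THI21 3.51-fold. Of the plasmid features, the reporter coding feature named for lacZ rose 2.16-fold in RNA (adjusted p = 0.00189) but did not pass in fragments (1.77-fold, adjusted p = 0.119). The coding feature named for HIS rose 1.28-fold in RNA (adjusted p = 0.0347) and 1.26-fold in fragments (0.00204), while its UTR feature did not pass in RNA (1.01-fold, adjusted p = 0.977), and the UTR feature named for lacZ rose 1.52-fold and 1.92-fold.

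In RNA, 14 of 28 glucose-repressed genes were lower, while 9 of 15 histone and S phase genes and 8 of 16 mitotic genes were higher. With an estimated correlation these list calls were lost in RNA (adjusted p = 0.111, 0.215 and 0.215) and in fragments (0.115, 0.284 and 0.284). A scaling between libraries moves all genes of a library alike, so it could shift these lists together but not apart. The gap within a library between the median of the glucose-repressed list and that of each other list grew by at least 0.868 on the log2 scale (SE 0.060) in RNA and fragments. This gap restates the medians of lists that were picked after they had moved apart, so it is no separate test of scaling. A candidate explanation is that pre-treated cultures were less far into glucose depletion when collected, and the median change of -0.0805 in ribosomal protein RNA, a list that did not pass, decides nothing on growth at this size. The harvest density was not given in the labels, so growth stage and a lasting effect of the drug cannot be told apart.

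In RNA, 17 of 50 amino acid biosynthesis genes were higher and 4 lower, while GCN4, the gene of their activator, was lower. More synthesis of Gcn4 is argued against as the cause, because fragments on GCN4 fell by 0.75 on the log2 scale (SE 0.11). A single library carrying the list is also argued against, since the highest camera adjusted p with any of 6 replicates left out was 9.19e-05. The list's call was lost with an estimated correlation (adjusted p = 0.465). Gcn4 is also regulated by its breakdown, and the activity of the protein may have differed, which counts of RNA and fragments did not measure.

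The 6 libraries or cultures of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 738 genes for RNA, 681 for fragments and 1 for translational efficiency. The highest of the other splits gave 0, 0 and 0 with edgeR. Each of those other splits mixed untreated and pre-treated cultures in both groups, so a treatment effect would widen their spread. Their counts of 0 are therefore no measure of the calls that arise without a treatment effect.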
